A study of Homo sapiens with 8 samples.

How the data were processed

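Total RNA of 8 xenograft tumour samples was measured on Toray 3D-Gene human miRNA arrays, 1 array per sample. The tumours were grown from CW-2, a human colon cancer cell line. Each sample is called a tumour below, although the labels number tissues and do not say whether each came from a separate tumour. By the labels, 4 tumours were controls and 4 came from the group given galectin-9, a lectin that binds beta-galactosides, at 90 µg. Route and schedule of dosing in animals were not given in the sources used here. The labels' protocols are shared with other parts of the study: they describe cultured cells and extraction from serum, while the source and sample type of every array name a xenograft tumour. The groups follow the treatment label. Nothing in the labels says that the numbered tissues came from separate tumours or animals, so the p-values measure only the spread between these samples, which may be technical.

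The deposited scanner files give, for each of 3200 spots per array, the mean foreground intensity and the median local background intensity in 1 channel, per the file headers, with no normalization. The labels' protocols name Cy5 as the dye, whereas the file headers name the channel 532; with 1 colour this does not affect a direction. Each array held 2019 miRNA probes, 925 blank spots, 24 negative-control spots and 16 spike-in control spots, and no spot was marked as an outlier. Of the probes, 15 name several miRNAs of like sequence and were kept as 1 probe. A second deposited table gives the authors' processed intensity of 2012 of these probes per array. Its method was not given in the sources used here. Compared with the scanner values, each column kept the order of the array's foreground means (Spearman correlation 0.999999 in each array), with no background subtracted. The column medians lay between 229.9 and 230 and the sorted values of the 8 columns differed by a median of 0.0449%, as after quantile normalization. The table was used as an alternative, and it holds no other per-sample columns. Of the 7 probes it does not list, 2 were among the miRNAs tested.

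The foreground was corrected for local background with the normexp model and an offset of 50, fitted on all spots. The miRNA probes were then quantile-normalized between the 8 arrays and taken to log2. The offset pulls fold changes of dim probes towards 1. A miRNA counted as detected on an array where its foreground exceeded the mean plus 2 SD of that array's negative-control spots, and 499 probes detected on at least 4 of the 8 arrays were tested. The design allowed blank or negative-control spots for this limit. Negative controls were taken because the blank spots of galectin-9 replicate 4 had an SD of 58.5 against 10.1 to 14.8 on the other arrays, and the blank limit was run as an alternative. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term), with Benjamini-Hochberg adjustment and a threshold of 0.05. Arrays have no read depth, so the number of arrays sets the precision. Per-array values were compared with exact two-sided permutation tests over the 70 assignments, whose smallest possible p is 0.0286.

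The main test, the lists of miRNAs and the alternatives planned were fixed before the data were examined. The miRNAs named one by one were those at adjusted p under 0.05 whose 4 treated and 4 control values did not overlap, the 15 with the largest rise and the 15 with the largest fall. Up to 4 measured members of each list with the smallest p were added, whether or not they passed, which gave 56 miRNAs in all. Any other miRNA named was chosen after its values were seen. The 14 lists hold 87 miRNAs, 86 of them on the array and 63 tested: the let-7 family, the miR-17/92 clusters, the miR-200 family, intestinal epithelial miRNAs, the p53-responsive miR-34 family, families that target BCL2 or MCL1, miRNAs raised in colorectal cancer, a hypoxia list, and markers of stromal fibroblasts and smooth muscle, endothelium, leukocytes, erythrocytes, skeletal muscle, and hepatocytes and serum. Some lists share members, such as miR-20a-5p and miR-18a-5p. Lists with at least 3 tested members, 8 in all, were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether a list's members move one way without comparing them with other miRNAs. Older names on the array (such as let-7c and miR-215) were matched by hand to the current names. A list member or miRNA not detected on any array of a group has only a bound there, given as "at least N-fold" from the higher of the lowest detected signal and its own value on each array.

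The procedure was tested on simulated data made from the real arrays' means and spread, with 200 miRNAs changed by known amounts and 463 tested. It recovered 22.0% of the 1.5-fold, 51.6% of the 2-fold and 93.5% of the 3-fold changes, and 4 of its 107 calls were false. The simulated noise was independent between miRNAs, and each change rose or fell at random. Real miRNAs vary together (estimated correlation 0.56 in the let-7 family) and 1 real array stood apart. The simulated rate of false calls therefore need not hold for the real arrays. Alternatives covered the background correction, the offset, the scaling between arrays, the filter on dim probes, the authors' processed values, the variance model, array weights, the replicate number as a block and each array left out. The files do not name slides, so the planned slide block could not be run as written. They give the position of each array on a slide of 4 positions. Controls lay at positions 1 and 3, treated tumours at 2 and 4, and each position held 1 group. Position could therefore not be separated from the groups. It was fitted as a random block, and the 8 ways to place the arrays on 2 slides were each fitted as a block. These fits, scaling by the spike-in controls, the blank limit, and the filter on all 8 arrays without scaling were added after the data were seen. No genome build or probe sequence was used here, so no coordinates are given and GC content was not checked. Near-identical miRNAs, such as the members of the let-7 family or miR-17-5p, miR-20a-5p, miR-20b-5p and miR-106a-5p, can bind each other's probes, so the values of single members are uncertain. Mature miRNAs of mouse and human are mostly identical in sequence, so a human array can also read RNA of mouse host cells.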

Results

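The series examined the effect of galectin-9 on colon cancer in cell lines and in a xenograft model. The arrays described here measured mature miRNAs in CW-2 tumours, 4 from controls and 4 from the group given 90 µg of galectin-9. Between 393 and 716 of the 2019 miRNA probes were detected per tumour, 248 probes were detected in all 8 tumours and 948 in none. Levels are log2 of the background-corrected, quantile-normalized intensity, errors are SD (n = 4 per group), and the error of a log2 change is its standard error.

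The comparison asks which miRNAs differed between treated and control tumours. Galectin-9 tumours had higher levels of let-7, miR-17, miR-200 and miR-192/194 family members, of miR-21-5p, and of the endothelial miR-126-3p, by 3.13-fold to 4.58-fold for the 15 largest rises. Levels of many miRNAs with high miRBase numbers, among them miR-1229-5p, miR-1275, miR-4294 and miR-4739, were lower by up to 2.53-fold. With limma, 213 of the 499 miRNAs tested changed at an adjusted p under 0.05, of which 84 rose and 129 fell. At least a 2-fold change was seen for 44 of those that rose and 23 of those that fell. The median log2 change was 1.03 among raised and −0.71 among lowered miRNAs. All 499 miRNAs had a median change of −0.12 on this scale; relative to it, the raised miRNAs lay at 1.15 and the lowered at −0.60. The values of the 4 treated and the 4 control tumours did not overlap for 223 miRNAs, 44.7% of those tested, where chance gives 2.86%.

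The division into raised and lowered rested on the scaling between arrays. Quantile normalization gave 84 raised and 129 lowered miRNAs, whereas scaling on the spike-in controls gave 21 raised and 259 lowered. The first spike-in control rose with slide position within each group. In controls its mean was 9738 and 10827 at position 1, against 15584 and 13153 at position 3. In treated tumours it was 12251 and 11792 at position 2, against 15703 and 13794 at position 4. The second rose less clearly, with overlap in treated tumours. Each position held 1 group, so spike-in scaling can carry a position effect. Without any scaling, limma called 0 miRNAs, with 169 at an unadjusted p under 0.05. Each of the 15 largest rises stayed positive and each of the 15 largest falls stayed negative with quantile, median, spike-in and no scaling. These signs are weak support, since the miRNAs were chosen for their size. Median, spike-in and no scaling also differ only by a shift common to all miRNAs of an array. From quantile to spike-in scaling, the median of the 15 rises went from 1.78 to 0.99, with 13 still called. That of the 15 falls went from −1.17 to −1.84. Plain background subtraction gave 57 raised and 40 lowered, and median scaling 57 and 76. Leaving out control replicate 3 reduced the calls to 66 raised and 45 lowered, and leaving out control replicate 2, the brightest array, reduced the lowered miRNAs to 81.

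The largest rise was that of miR-20a-5p (MIMAT0000075), a member of the oncogenic, MYC-induced miR-17/92 transcript, from 8.89 ± 0.64 in controls to 11.09 ± 0.19 in treated tumours, a log2 change of 2.19 ± 0.29 (4.58-fold, adjusted p = 0.0014). Its relatives miR-106a-5p, miR-17-5p and miR-20b-5p rose by 1.91 ± 0.23, 1.88 ± 0.24 and 1.86 ± 0.31. Of the let-7 miRNAs, which repress RAS and HMGA2 transcripts, let-7a-5p rose by 2.08 ± 0.26, let-7c by 2.06 ± 0.52, let-7f-5p by 1.71 ± 0.29 and let-7d-5p by 1.65 ± 0.33. Closely related probes of these families can bind each other's targets, so single members are uncertain. The most precise of the 15 largest rises was that of miR-4284 (MIMAT0016915), from 10.60 ± 0.22 to 12.39 ± 0.12, with a log2 change of 1.78 ± 0.14 and the smallest adjusted p of all, 0.0002. The other large rises were miR-26a-5p (1.92 ± 0.24), miR-126-3p (1.77 ± 0.33), the epithelial miR-200a-3p (1.74 ± 0.26), miR-125b-5p (1.72 ± 0.46), the intestinal miR-192-5p (1.70 ± 0.28) and miR-21-5p (1.65 ± 0.28), an miRNA abundant in many carcinomas. Adjusted p-values of these 15 miRNAs ranged from 0.0002 to 0.019. Treated replicate 3 stood apart for miR-125b-5p, at 10.63, where the other treated tumours lay between 8.30 and 8.63, and its call was lost without control replicate 2 or 3.

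The largest fall was that of miR-1229-5p (MIMAT0022942), from 9.37 ± 0.19 to 8.03 ± 0.55, a log2 change of −1.34 ± 0.26 (2.53-fold lower, adjusted p = 0.0057). It was followed by miR-1275 at −1.33 ± 0.22, miR-4632-5p at −1.32 ± 0.46 and miR-4294 at −1.32 ± 0.32. For miR-642b-3p, miR-4732-5p and miR-4739 the log2 changes were −1.21 ± 0.35, −1.20 ± 0.34 and −1.20 ± 0.28. The change was −1.17 ± 0.41 for miR-1233-1-5p and −1.17 ± 0.23 for miR-92a-2-5p, which comes from the other arm of a miR-92a precursor and was detected in 4 controls but only 2 treated tumours. Changes of −1.13 ± 0.23 for miR-4417, −1.13 ± 0.22 for miR-3197, −1.11 ± 0.13 for miR-4459, −1.09 ± 0.22 for miR-197-5p (detected in 3 treated tumours), −1.08 ± 0.18 for miR-6085 and −1.07 ± 0.21 for miR-4532 completed the 15. Adjusted p-values ranged from 0.0014 to 0.047. The falls of miR-4632-5p and miR-1233-1-5p were the least precise, with adjusted p of 0.044 and 0.047, and control replicate 1 reached 11.19 for miR-4632-5p while the other controls lay between 9.39 and 9.50. The call for miR-4632-5p was lost in 7 and that for miR-1233-1-5p in 6 of the 8 fits that left out 1 array, and those of miR-642b-3p and miR-4732-5p were lost without control replicate 2 or 3.

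**Figure D1:**
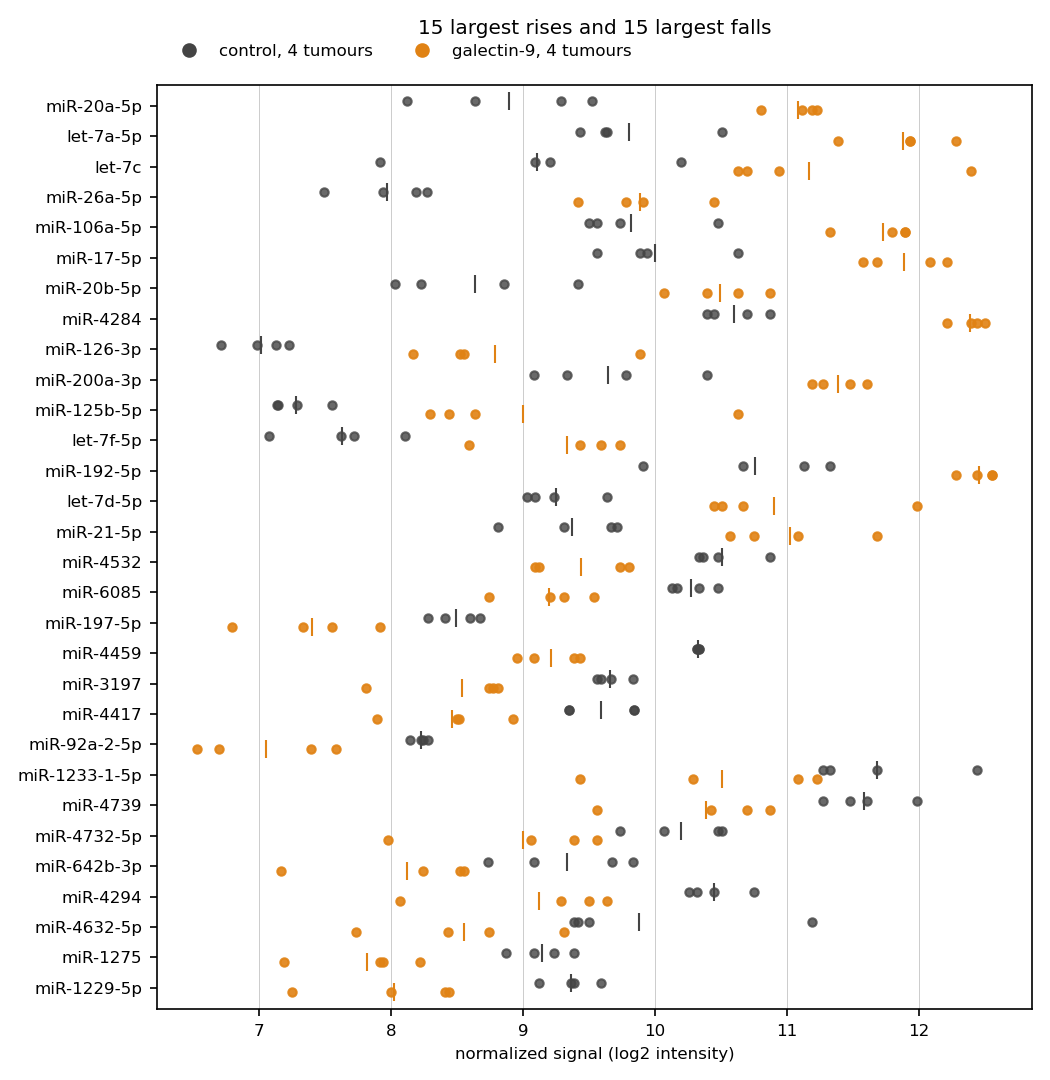
Normalized signal (log2 intensity, horizontal axis) of the 15 miRNAs with the largest rise and the 15 with the largest fall. Each point is 1 sample, black for control and orange for galectin-9 (4 each), and vertical ticks mark group means. The groups do not overlap for any of the 30 miRNAs, from miR-20a-5p (8.89 against 11.09) to miR-1229-5p (9.37 against 8.03).

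All 8 tested let-7 family members rose, with a median log2 change of 1.49 (1.61 relative to all miRNAs), and all 8 stayed positive under each scaling; with spike-in scaling the median was 0.74 and 5 of the 8 were called, and without scaling 0 were called. Besides those named above, let-7g-5p rose by 1.33 ± 0.15 and let-7e-5p by 0.99 ± 0.16. The same 8 passed when adjusted over the list alone, and camera gave an adjusted p of 1.24e-05 (adjusted p = 0.085 with an estimated correlation). In the miR-17/92 clusters 11 of 12 tested members rose, 12 when adjusted over the list alone, with a median of 0.96 (1.07 relative to all miRNAs); with median scaling 7 were called, with spike-in scaling 4 with a median of 0.22, and without scaling 0 with a median of 0.44. The exception was miR-92a-3p at 0.48 ± 0.18 (adjusted p = 0.053), and it and miR-25-3p turned negative without scaling (−0.15 and −0.21) and with spike-in scaling (−0.36 and −0.43). Camera gave an adjusted p of 2.93e-07 for this list (adjusted p = 0.071 with an estimated correlation).

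Both epithelial lists were higher in treated tumours with quantile scaling, whereas with spike-in scaling 0 of their members were called and the medians were 0.11 for the miR-200 family and 0.28 for the intestinal list. All 5 members of the miR-200 family, which represses ZEB1 and ZEB2 and keeps cells epithelial, rose with a median of 0.84, including miR-200b-3p at 1.29 ± 0.20, miR-141-3p at 0.80 ± 0.16 and miR-429 at 0.51 ± 0.17; with spike-in scaling miR-200c-3p turned negative, at −0.21. The call for miR-429 was lost without control replicate 1 or 3 and without galectin-9 replicate 1 or 2. All 4 tested intestinal epithelial miRNAs rose with a median of 1.15, among them miR-194-5p, from 11.20 ± 0.27 to 12.70 ± 0.06, and miR-215 at 0.79 ± 0.15, while the rise of miR-375, 0.54 ± 0.14, became −0.07 with spike-in scaling. The same 5 and 4 passed when adjusted over the list alone. Camera's adjusted p was 0.00060 for the miR-200 family and 0.00046 for the intestinal list (adjusted p = 0.071 for both with an estimated correlation). The remaining intestinal member, miR-147b, was detected in 2 controls and no treated tumour and was not tested.

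Among families that target the anti-apoptotic transcripts BCL2 or MCL1, 7 of 8 tested members rose, also 7 when adjusted over the list alone, with a median of 1.05; all 8 were positive under each scaling, but with spike-in scaling the median was 0.35 and 1 was called, and without scaling 0 were called. Of the BCL2-targeting group miR-16-5p rose by 1.64 ± 0.27 and miR-15a-5p by 0.91 ± 0.20, and of the MCL1-targeting group miR-29b-3p rose by 1.37 ± 0.18 and miR-29a-3p by 1.19 ± 0.18. Another member, miR-195-5p, was detected in 4 treated and 0 control tumours and was at least 1.86-fold higher (adjusted p = 0.015), and miR-497-5p, at 0.51 ± 0.32, did not pass. Camera gave this list an adjusted p of 2.76e-05 (adjusted p = 0.085 with an estimated correlation). The single tested member of the p53-responsive miR-34 family, miR-34a-5p, rose by 1.04 ± 0.15 (adjusted p = 0.0021), a call lost with spike-in scaling (0.42) and without scaling (0.64). The hypoxia-induced miR-210 had a change of 0.11 ± 0.17 (adjusted p = 0.61), which was −0.42 without scaling and −0.64 with spike-in scaling.

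Of 10 tested miRNAs on the list raised in colorectal cancer, 7 rose and 3 did not pass, also when adjusted over the list alone, with a median of 0.65. Next to miR-21-5p and miR-20a-5p, miR-221-3p rose from 9.21 ± 0.19 to 10.21 ± 0.21 and miR-222-3p by 0.70 ± 0.13. The 3 that did not pass were miR-21-3p at 0.16 ± 0.15, miR-96-5p at 0.29 ± 0.12 and miR-183-5p at 0.01 ± 0.11. With spike-in scaling the median was 0.017, 2 members rose and 1 fell: these 3 and miR-182-5p turned negative, and miR-183-5p, at −0.44, passed (adjusted p = 0.043). Camera gave an adjusted p of 2.76e-05 (adjusted p = 0.071 with an estimated correlation).

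Among markers of cells other than the tumour cells, 5 of 8 stromal fibroblast and smooth muscle miRNAs rose, and 8 when adjusted over the list alone, with a median of 1.17; miR-99a-5p, miR-100-5p and miR-214-3p did not pass (adjusted p = 0.078, 0.061 and 0.079). With spike-in scaling the median was 0.58 and 4 were called, and without scaling 0 were called. Beside miR-125b-5p, the mesenchymal miR-199a-5p rose by 1.29 ± 0.27, miR-143-3p by 1.17 ± 0.27 and the probe shared by miR-199a-3p and miR-199b-3p by 1.17 ± 0.15, each detected in 4 treated tumours but in only 2, 2 and 1 controls. Galectin-9 replicate 3 stood apart at 9.17 for miR-199a-5p (7.98 to 8.02 in the other treated tumours), 8.98 for miR-143-3p (7.65 to 7.96) and 9.15 for miR-99a-5p (7.11 to 7.52). The member miR-214-3p, at 0.27 ± 0.11, turned to −0.10 with spike-in scaling. Camera's adjusted p for the stromal list was 0.00017 (adjusted p = 0.12 with an estimated correlation). The endothelial miR-126-3p rose from 7.01 ± 0.22, detected in 2 controls, to 8.79 ± 0.76, detected in 4 treated tumours, with galectin-9 replicate 3 at 9.89 and the others between 8.17 and 8.56. The other endothelial member, miR-126-5p, was detected in 1 treated and 0 control tumours and was not tested.

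Of 4 tested leukocyte miRNAs, miR-155-5p rose by 0.89 ± 0.19, the only one to pass, also when adjusted over the list alone. With spike-in scaling and without scaling, 0 of the 4 were called. The neutrophil marker miR-223-3p had a change of 0.57 ± 0.31, miR-146a-5p of 0.48 ± 0.19 and the lymphocyte miRNA miR-150-5p of 0.28 ± 0.17. Of the members not tested, miR-142-3p was detected in no tumour and miR-142-5p in 1 control and 1 treated tumour. The third, miR-342-3p, was detected in 3 treated and 0 control tumours. The list's median was 0.52 and camera's adjusted p 0.031 (adjusted p = 0.085 with an estimated correlation). This call was lost with median scaling, with array weights, without control replicate 1 and without galectin-9 replicate 3, and the median became −0.07 with spike-in scaling. Among erythrocyte miRNAs, miR-451a had a change of 0.73 ± 0.65 and miR-486-5p of −0.16 ± 0.26, and neither passed; with spike-in scaling miR-451a was −0.16 and miR-486-5p, at −0.74, passed as lower. The muscle miRNA miR-133b had a change of 1.19 ± 0.66 (adjusted p = 0.17). Treated replicate 3 was at 10.36 and the other treated tumours between 6.98 and 7.28, against a control mean of 6.78. The liver and serum miRNA miR-122-5p was detected in none of the 8 tumours.

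**Figure D2:**
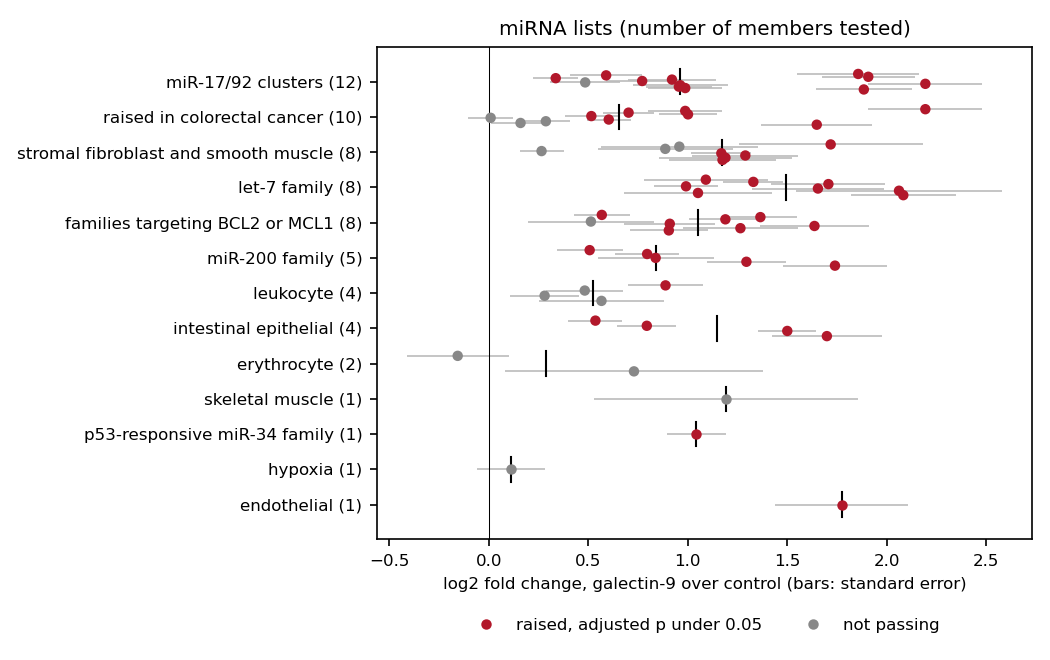
Log2 fold change of galectin-9 over control tumours (horizontal axis, quantile scaling) for each tested member of the fixed lists, with the number tested in brackets. Points are miRNAs, bars are standard errors, red marks an adjusted p under 0.05 and black ticks are list medians, such as 1.49 for the let-7 family and 0.52 for leukocyte miRNAs, the latter −0.07 with spike-in scaling.

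In all, camera called 8 of 8 lists raised with its preset correlation. With an estimated one it called 0 of 8, with an unadjusted p under 0.05 for 4 lists. Fry called 8 of 8. All tested members of these lists have miRBase numbers below 1000, a class with a median change of 0.22. The miRNAs numbered 1000 and above, 247 of the 499 tested, had a median of −0.39. Camera compares a list with all other tested miRNAs, so its calls also carry this class difference. So do the medians given relative to all miRNAs. No list was compared with its own class alone. Of the 35 ways to split the 8 arrays into equal groups, 10, the real one included, gave 8 shifted lists. This comparison therefore does not separate the list calls from chance. It cannot decide the question either, since splits that swap few arrays keep part of the group difference. In every other split limma called 0 miRNAs, with at most 78 at an unadjusted p under 0.05.

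Direction differed by miRBase number, which broadly follows the order of discovery; this division was made after the values were seen. Of 252 tested miRNAs numbered below 1000, 77 rose and 24 fell, and of 247 numbered 1000 and above, 7 rose and 105 fell. Median log2 changes were 0.22 and −0.39 with quantile scaling, and −0.25 and −0.90 with spike-in scaling, which shifts all miRNAs of an array alike and so leaves the sign of a class open. The gap between the classes was 0.62 and its size depended on the processing, from 0.09 without a filter on dim probes, 0.34 with the blank limit and 0.39 with the authors' values to 1.13 with the filter on all 8 arrays, 1.25 with that filter and no scaling, and 1.71 with plain subtraction. Within each tumour, the median level of the first class minus that of the second was −0.30 ± 0.08 in controls and 0.40 ± 0.22 in treated tumours (n = 4 each). The 7 high-numbered miRNAs that rose were miR-4284, miR-1260b, miR-4286, miR-1260a, miR-5100, miR-1273g-3p and miR-3607-3p, by 1.78, 1.58, 1.20, 1.21, 1.17, 1.12 and 0.44. Lower-numbered miRNAs that fell included miR-149-3p at −0.79 ± 0.14, miR-423-5p at −0.62 ± 0.17 and miR-663a at −1.07 ± 0.25.

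**Figure D3:**
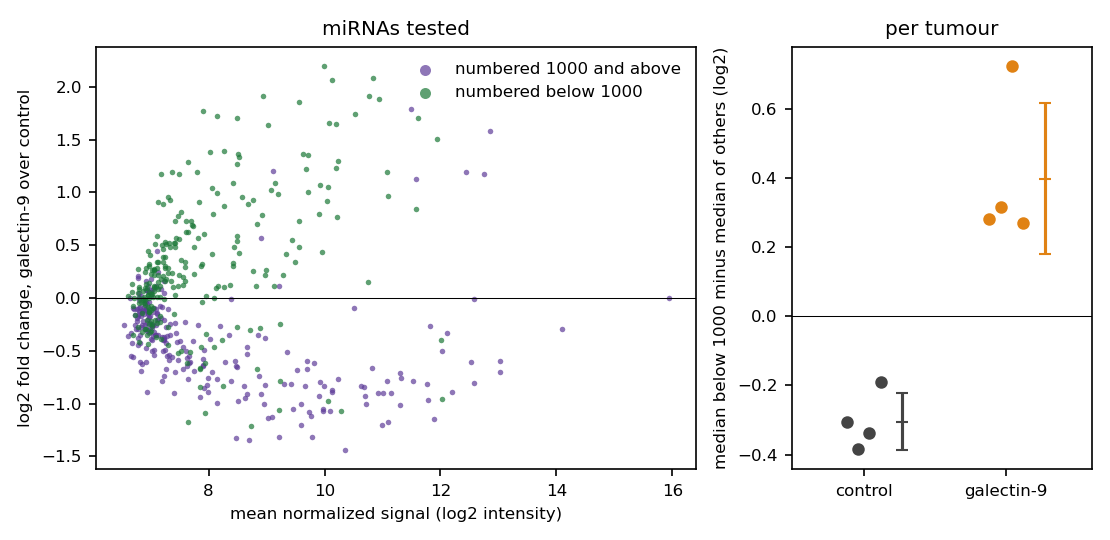
Left, log2 fold change against mean normalized signal (log2 intensity) for the 499 tested miRNAs, green for numbers below 1000 (median 0.22, −0.25 with spike-in scaling) and purple for 1000 and above (median −0.39). Right, for each tumour the median of the first class minus that of the second, with mean and SD beside the points. All 4 galectin-9 tumours lie above all 4 controls.

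The number of miRNAs detected and the signal of those detected in all tumours differed between groups by less than the spread between tumours. The number of miRNAs detected was 548 ± 117 in controls and 510 ± 108 in treated tumours (n = 4 each, exact permutation p = 0.63). The median log2 raw signal of the 248 miRNAs detected in all tumours was 9.35 ± 0.61 and 8.99 ± 0.41 (n = 4 each, exact permutation p = 0.46). Over all miRNA probes, most of them undetected, the difference in overall signal per array was small, −0.045, but all 4 treated arrays lay below all 4 controls (exact permutation p = 0.0286). The negative-control spots, which are not miRNA probes, likewise averaged 212.8 to 217.7 on treated and 218.0 to 225.1 on control arrays. Detection limits ran from 228.9 to 240.8 on treated and from 236.2 to 246.5 on control arrays. Counts of tumours in which an miRNA was detected therefore also depend on a background that differed between groups. Control replicate 2 was the brightest array at 10.24 and galectin-9 replicate 3 the dimmest at 8.42. The first principal component held 72.0% of the variance and placed controls between −8.88 and −5.79 and treated tumours between 3.12 and 15.97, the last value being galectin-9 replicate 3. Without that array 83 miRNAs rose and 115 fell. The brightest probe, miR-4454, was saturated in 2 treated tumours.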

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

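The tests of the cell mix, of a shared RNA axis and of the offset were chosen after the results were seen; the tests of slide position and of other splits were chosen before. With 118 groups of 4 examined for a sample far from the rest, chance gives about 5.9 and 9 were found. Galectin-9 replicate 3 accounted for most of them, so its departures are the first pattern below.

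Galectin-9 replicate 3 lay far from the other treated tumours for miR-125b-5p (10.63), let-7d-5p (11.99), miR-199a-5p (9.17), miR-133b (10.36) and miR-3197 (7.81). It also had the largest median of lower-numbered minus higher-numbered miRNAs, 0.72, where the other treated tumours had 0.27 to 0.32. Its departure from the rest of its group correlated across the 499 miRNAs with the difference between groups computed without it (r = 0.55; miRNAs are not independent replicates). The leading axis of the 4 controls did not follow that difference (r = −0.02). A shared axis such as RNA integrity or small-RNA yield may therefore contribute, and it cannot be told apart from a stronger response in that tumour, since 1 array carries it.

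The opposed shift of lower-numbered and higher-numbered miRNAs was weighed against a different mix of tumour and host cells and a gradient along the slide. A changed mix as the whole cause needs epithelial and host markers to move apart. With quantile scaling, however, the 9 tumour-epithelial miRNAs had a median change of 0.84 (bootstrap SE 0.30). The 9 stromal and endothelial ones had 1.17 (0.13). These SEs resample the miRNAs, which vary together, and not the tumours, so they do not measure the spread between tumours. With spike-in scaling the medians were 0.19 (0.17) and 0.60 (0.15), so the epithelial median lay near 0 and a changed mix stays open. A gradient needs the change over 2 positions within each group to follow the group difference with a slope of 1 or more. This limit follows because the groups lie 1 position apart on average. The slopes were 0.08 in controls and −0.21 in treated tumours, and the highest single pair gave 0.22. This argues against a gradient as the source of the shift across miRNAs, although the first spike-in control itself rose with position. An effect of alternating positions stays open, because odd positions held only controls and even positions only treated tumours, and so do unspecific binding by probes of high-numbered miRNAs and an effect of galectin-9, which were not tested.

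Members of the miR-17/92 transcript rose by unequal amounts, from 2.19 for miR-20a-5p to 0.48 for miR-92a-3p. The difference between these members, chosen for their gap, was 1.71 with the offset and 2.04 with plain background subtraction. This does not decide whether compression of dimmer probes by the offset contributes to the unequal rises, since miR-20a-5p was the dimmer of the pair in controls (8.89 against 9.31) and removing compression could only widen their gap. Binding of related miRNAs to the miR-20a-5p probe and unequal maturation stay open and were not tested.

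Single values far from the rest of their group were also found for miR-4632-5p in control replicate 1 (11.19), for miR-106a-5p in galectin-9 replicate 1 (11.33, lower than the other treated tumours) and for the probe shared by miR-199a-3p and miR-199b-3p in galectin-9 replicate 2 (8.08). Outside the miRNA probes, 22 further probes of unstated content, named S-Probe on the array, were examined. S-Probe1018 was brighter in all 4 treated than in all 4 control tumours, with a mean raw intensity of 768.5 against 542.4. Chance gives 0.31 probes separated in this direction and as many in the other, and the direction was not set beforehand.

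Chance assignment was examined with all 35 splits of the 8 arrays into equal groups. Only 1 of the 35, the real one, gave as many changed miRNAs (213, highest other 0), as many raised (84, highest other 0) or as many lowered (129, highest other 0). This is the smallest share that 35 splits can give. A difference between the real groups also enters the error of the other splits, which mix treated and control arrays. The counts therefore went with the group labels, but this does not exclude chance. The other splits, for which limma called 0, had at most 78 miRNAs at an unadjusted p under 0.05, against 261 in the real one. For the number of lists shifted, 10 of the 35 gave 8 (highest other 8), so chance is not excluded. Splits that swap few arrays keep part of the group difference, so this count cannot decide the question.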

How the results depend on the processing

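Spike-in scaling, the 8 slide placements, position as a random block, the blank limit, and the filter on all 8 arrays without scaling were chosen after the data were seen. Across all alternatives, the log2 changes of the 56 named miRNAs kept direction and side of the threshold in 1479 comparisons, lost significance in 162, gained it in 6 and reversed in 9. With the slide placements, the replicate block, position as a random block, or trend and robust variance, the log2 changes equal those of the main fit. The filters and the blank limit also leave them unchanged when scaling is kept. Those comparisons could move only the significance, so they say nothing about direction. The counts of 213 changed, 84 raised and 129 lowered stayed within 1.5 times with offset 16, both filters, the authors' values, trend and robust variance, array weights, the blank limit and the slide placements (189 to 215). Position as a random block (217 changed) is no test of position, since each position held 1 group and its estimated correlation of −0.017 left the fit nearly unchanged; it is among the comparisons counted above. Plain subtraction gave 97 changed (57 raised, 40 lowered) and median scaling 133 (57 raised, 76 lowered). Of the 56 named miRNAs, 13 lost significance with plain subtraction and 2 with median scaling. Without scaling limma called 0 in each direction (169 at an unadjusted p under 0.05), and 0 also with the filter on all 8 arrays (107); spread in array brightness, up to 10.24 against 8.42, then enters the error. Spike-in scaling gave 280 changed (21 raised, 259 lowered), and the median of all miRNAs moved from −0.12 to −0.54. Leaving out 1 array gave 111 to 209 changed, 66 to 83 raised and 45 to 129 lowered, lowest without control replicate 3 (111, 66 and 45); without control replicate 2, 81 were lowered. Calls of named miRNAs lost on leaving out 1 array were those of miR-4632-5p, miR-1233-1-5p, miR-642b-3p, miR-4732-5p, miR-125b-5p and miR-429; miR-223-3p, miR-133b and miR-146a-5p passed without control replicate 2, galectin-9 replicate 3 and galectin-9 replicate 4.

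The leukocyte median of 0.52 was 0.59 with median scaling, 0.50 with array weights and 0.42 to 0.60 leaving out 1 array, its call lost in the first 2 and without control replicate 1 (0.52) or galectin-9 replicate 3 (0.42). It reversed to −0.068 with spike-in scaling, where camera, which compares with other miRNAs, still gave a rise. The medians of the other 7 lists tested stayed positive. Among the named miRNAs, reversals with spike-in scaling were miR-375 (−0.073), miR-210, the single tested hypoxia member (−0.64), miR-146a-5p (−0.043), miR-223-3p (−0.19), miR-150-5p (−0.094) and miR-451a (−0.16); other list members that turned were miR-92a-3p, miR-25-3p, miR-200c-3p, miR-21-3p, miR-96-5p, miR-182-5p, miR-183-5p and miR-214-3p. The erythrocyte median of 2 members, 0.29, became −0.45, and −0.23 without scaling. Without scaling miR-210 was −0.42 with either filter, and miR-486-5p ranged from −0.39 to 0.063 leaving out 1 array, the latter without galectin-9 replicate 4. The difference in overall signal per array, −0.36, was −0.045 over all probes (exact permutation p = 0.0286) and −0.51 to −0.06 leaving out 1 array; the difference in the number of miRNAs detected per array, −38.2, ranged from −85 to 17.75, positive without control replicate 2 (17.75) and without galectin-9 replicate 4 (0.67). The cause was not tested for these.

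No uniform pairing by replicate number was seen. Deviations of same-numbered samples correlated at 0.06, 0.38, −0.17 and 0.07, and only control replicate 2 correlated best with its own number. These few values do not exclude a shared condition, since same-numbered arrays lay at neighbouring slide positions (1 and 2, or 3 and 4). With the replicate block 194 miRNAs changed, 80 raised and 114 lowered; of the named miRNAs, miR-1233-1-5p and miR-429 no longer passed. Signal over background limits dim miRNAs: 948 probes were detected nowhere.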

Other observations

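The families and miRNAs below were chosen after their values were seen, and no cause was tested. Several conserved families outside the fixed lists were higher in galectin-9 tumours with quantile scaling, but without scaling 0 of their members were called. All 5 tested members of the clustered miR-23, miR-24 and miR-27 families rose, with a median log2 change of 1.09 that stayed positive under each scaling (0.31 with spike-in scaling, where 0 were called), led by miR-23b-3p at 1.36 ± 0.32 and miR-23a-3p at 1.22 ± 0.31. Of the 5 miR-30 family members 4 rose, with a median of 0.87 (0.21 with spike-in scaling, where 1 was called), from miR-30b-5p at 1.40 ± 0.20 to miR-30e-5p at 0.73 ± 0.17, while miR-30a-5p, at 0.73 ± 0.34, did not pass. Both members of the miR-103 and miR-107 pair rose, miR-103a-3p by 1.23 ± 0.23 and miR-107 by 1.07 ± 0.19, as did miR-26b-5p by 0.93 ± 0.16, and their families stayed positive under each scaling, with 0 of 2 and 1 of 2 called with spike-in scaling.

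By contrast, 2 of 7 tested members of the miR-130, miR-301 and miR-148 families rose, miR-148a-3p by 0.69 ± 0.14 and miR-301a-3p by 0.63 ± 0.13, and the median of 0.34 became −0.06 with spike-in scaling. Of 2 tested miR-181 family members 1 rose, miR-181a-5p by 0.52 ± 0.19, and the median of 0.35 became −0.13 with spike-in scaling. Muscle miR-133a, below the filter, was detected in 3 treated and 0 control tumours, and was at least 1.95-fold higher by its bound, untested. The let-7 relative miR-98-5p, also untested, was detected in 3 treated and 0 control tumours. The brightest miRNAs among those that fell were miR-5787 at −0.70, miR-4516 at −0.61 and miR-1234-5p at −0.81.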
